A study of Danio rerio and Mus musculus with 14 samples.

How the data were processed

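The 14 libraries were ATAC-seq libraries of wild-type zebrafish (strains AB, Tu and TL) and mouse (B6CBAF1) embryonic tissue. Per the labels' protocols, tissues were dissociated with collagenase and 50000 cells entered each reaction. Groups and replicate numbers were taken from the sample titles. The submitters corrected the stage of 3 fish libraries, cloaca, tail bud and trunk, from 16 to 30 hours post-fertilization (hpf), and stated that the data did not change. The peak names inside those 3 files still carry the earlier stage, and the corrected stage of 30 hpf was used.

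Each deposited file was a MACS2 narrowPeak list of 1 library, not of pooled replicates. Per the submitters' processing notes, the tools were cutadapt 4.1, Bowtie2 2.4.5, SAMtools 1.16.1, Picard 3.0.0, bedtools 2.30.0 and MACS2 2.2.7.1, and the genome builds danRer11 and mm39. The settings of the peak caller, any shift of reads for the transposase and the numbers of reads are not given in the sources used here. The deposited score column holds 10 times the −log10 q rounded down, as the values show, and was not used. The deposited fold enrichment is the ratio of the peak summit to the caller's own background in that library. The deposited −log10 p and −log10 q values are the authors' own for each peak and grow with sequencing depth. The lowest −log10 q lay between 1.30 and 1.31 in all files, close to a q threshold of 0.05. The deposited summit offset in bp gave the position of each summit within its peak.

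These scores and folds are the authors' values per peak and were used only to rank peaks within a list. Several summits of 1 interval were joined to 1 peak with its best summit, which left 136914 to 206076 peaks in fish and 77875 to 111033 in mouse. Peaks on unplaced scaffolds were left out, 1.50% to 1.78% of a fish list and 0.042% to 0.062% of a mouse list, and no list held a mitochondrial peak. The 25 fish chromosomes, and the 19 autosomes, X and Y of the mouse, were kept. Every list was then shortened to the length of the shortest of its species by −log10 p, 134472 peaks in fish and 77827 in mouse, which kept 66.2% to 100% of a fish list and 70.1% to 100% of a mouse list. The 50000 best peaks of each list were called strong. The weakest strong peak had a −log10 p between 9.18 and 34.1 in fish and between 6.76 and 10.1 in mouse, so that the same rank stands for different evidence in different libraries. A peak counted as shared when a peak of the other list overlapped it by at least 1 bp.

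Each comparison counted, per window of 100 kb, the strong peaks of the first library with no peak in the second, less the reverse. A window was called when this net number had 1 sign and passed the replicate spread in every pair of libraries. The spread was the 99.5th percentile of the net number over windows between replicates, 2 peaks in fish from the 3 posterior trunk pairs and 3 in mouse from the male and the female pair, and also the largest net number of that window between replicates. Comparisons of 30 hpf tissues have 1 library on each side and borrowed the posterior trunk spread. No p-value was computed for windows. The rule was also applied to the replicates themselves, each pair against the spread of the replicate pairs left. It called 27 windows between posterior trunk replicates 1 and 2, 18 between 1 and 3 and 0 between 2 and 3, at a threshold of 2. It called 16 between males, at a threshold of 4, and 110 between females, at 3. In the comparisons all pairs had to pass. The posterior trunk pairs share libraries, and replicates 2 and 3 share 99.9% of strong peaks. The pair of 1 and 2 was thus judged against its near copy, the pair of 1 and 3, and the reverse. The 27 and 18 are therefore low by construction and give no background rate.

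The design, the alternatives and the rule for named items were fixed before the data were examined. They assumed genes as units. No genome or annotation of danRer11 or mm39 was used here, so windows took the place of genes after the files were seen, and gene lists, motifs, hox promoters and the hoxda and HoxD landscapes were not analysed here. The rule for named items, carried over to windows, names up to 8 called windows per direction and comparison with the largest mean net number, ties in genome order, and the 3 best-ranked peaks of each set found in 1 tissue of 30 hpf. The text gives some of these. The tables of gene names held 49597 genes of another zebrafish assembly (GRCz12tu), from which no coordinate was taken; it served in 1 test of the closing section, for which chromosomes hold hox genes.

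Regions of 16 hpf were made by merging the lists of its 6 libraries. A region belonged to the posterior set with a strong peak in all 3 posterior trunk libraries and no peak in the other 3. Its presence at 30 hpf was a peak of the shortened list in each tissue, with a 95% Wilson interval. Tissue-only peaks of 30 hpf were strong peaks of 1 tissue with no peak in the other 3. Differences between single values were tested with exact two-sided permutation tests.

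The window rule was tested on simulated lists, all drawn from 1 real list per species, posterior trunk replicate 2 and male replicate 1. Noise was set so that replicates shared as much as in the data on average. The shares were 98.1% against 98.2% for posterior trunk against head and 80.1% against 80.2% for male against female. In the fish comparison it recovered 36.0%, 80.0%, 88.0% and 100.0% of 50 windows each from which 3, 4, 5 and 6 peaks were taken, with 0 calls in 12428 other windows. In the mouse comparison it recovered 0.0%, 6.00%, 20.0% and 60.0%, with 0 calls in 20760. The simulated lists of a species had the same source and the same noise, so the sides did not differ in strength as the real lists do. The 0 calls therefore give no rate of false calls for the data.

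Alternatives were the full deposited lists, lists of 100000 peaks (fish only), 20000 strong peaks, order by fold enrichment, an overlap of 50% of the peak, each replicate left out in turn, and in mouse autosomes alone and only same-numbered pairs. Windows of 50 and 200 kb were added after the data were seen. The work used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.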

Results

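Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in 14 libraries from wild-type embryos. The 10 zebrafish libraries came from 8 groups. At 16 hours post-fertilization (hpf) the groups were head, rhombomeres (the segments of the hindbrain), anterior trunk and posterior trunk, the last with 3 replicates. At 30 hpf they were head, trunk, tail bud (the growth zone at the posterior tip) and cloaca (the common posterior opening of the gut and the kidney ducts), each with 1 library. The 4 mouse libraries were 2 male and 2 female replicates of the urogenital sinus at embryonic stage E18.5, the ventral chamber from which bladder and urethra arise. The series title places these tissues in a study of a cloacal regulatory landscape and its later use in digits and genitals.

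The deposited lists held 136914 to 206076 peaks per fish library and 77875 to 111033 per mouse library. Read counts are unknown, so no detection floor can be given, and the lists were compared at 1 length per species, 134472 peaks in fish and 77827 in mouse. Strong peaks were the 50000 best of each list. All positions refer to danRer11 for fish and mm39 for mouse. No gene annotation of these builds was used here, so regions are named by position and not by gene. Nothing in the labels says that replicates came from separate animals or pools, so the spread between them may be technical. Values for groups with 1 library have no replicate check.

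Compared in pairs, most strong peaks of any fish tissue overlapped a peak of the other tissue. Of the strong peaks of posterior trunk, 94.2% ± 0.19 (SD, n = 3) had a peak in anterior trunk, its neighbour, against 87.0% ± 0.53 in rhombomeres and 85.1% ± 0.17 in head at 16 hpf. At 30 hpf the head shared 95.3% of the strong peaks of the trunk, 87.7% of those of the tail bud and 87.3% of those of the cloaca. The cloaca had peaks at 92.3% of the strong peaks of the tail bud, and the tail bud at 90.9% of those of the cloaca. Posterior trunk at 16 hpf contained 91.1% ± 2.18 of the strong peaks of the 30 hpf tail bud, 88.4% ± 2.72 of those of the cloaca, 86.2% ± 2.5 of those of the trunk and 84.3% ± 1.92 of those of the head (SD, n = 3). In the reverse direction the strong peaks of posterior trunk were found at 85.1% ± 0.60 in tail bud, 84.3% ± 0.68 in head, 83.9% ± 1.08 in trunk and 83.8% ± 1.07 in cloaca (SD, n = 3), without that order. Between posterior trunk replicates the share was 98.2% ± 1.60 (SD, 6 ordered pairs), with 96.2% as the lowest. Posterior trunk had at most 94.3% in another tissue, but anterior trunk had 95.6% ± 1.95 in posterior trunk (SD, n = 3), with 97.2% in replicate 2, so the shares of replicates and of neighbouring tissues overlapped. Across all fish libraries 336750 regions were found, of which 41646 had a peak in all 10 libraries and 126137 in 1 library. Of the regions with a strong peak in any library, 40.3% had a peak in all 10. With all peaks of the shortened lists counted in place of strong ones, 53.5% to 80.2% were shared between 2 libraries.

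The posterior trunk replicates were not equally close. Replicates 2 and 3 shared 99.9% ± 0.086 of strong peaks (2 ordered pairs) and replicate 1 shared 97.4% ± 1.23 with them (4 ordered pairs). Replicates 2 and 3 had lists of different length, 206076 and 176479 peaks, and were kept as separate replicates, as labelled. They may be 2 sequencings of 1 library, and values with n = 3 or 3 pairs would then rest on 2 samples. Whether they differ by more than sampling noise cannot be tested without read counts.

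**Figure D1:**
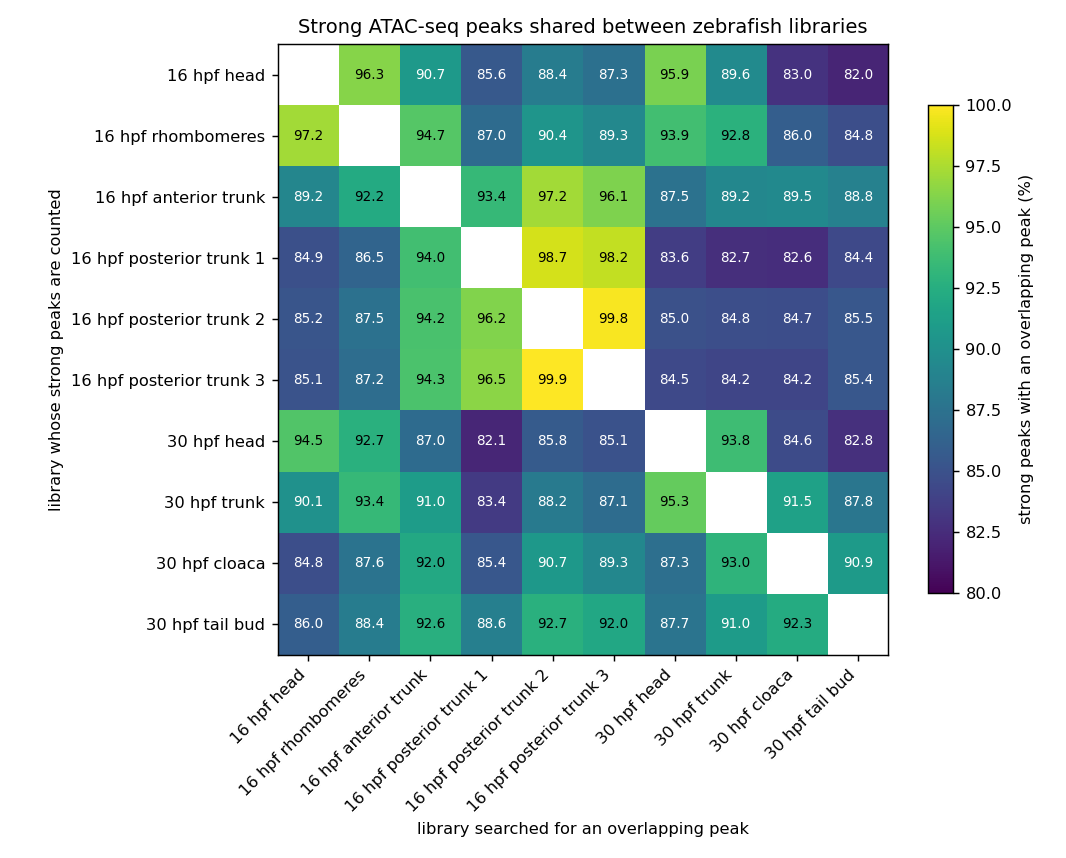
Percent of the strong peaks of each fish library (row) that overlap a peak of another library (column), in lists of equal length. The 6 values between posterior trunk replicates lie between 96.2% and 99.9%, and the mean share of posterior trunk in head at 16 hpf is 85.1%.

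The 16 hpf comparison of posterior trunk with head asks which parts of the genome are open in the body axis and closed in the head. The strongest differences were dense groups of posterior trunk peaks in a few 100-kb windows. On chromosome 3 from 23.6 to 23.7 Mb the posterior trunk had 21.0 ± 2.00 strong peaks (SD, n = 3) and the head 4. On chromosome 9 from 1.9 to 2.0 Mb it had 19.3 ± 2.31 against 4, and on chromosome 23 from 36.1 to 36.2 Mb 16.0 ± 0.0 against 2. Chromosome 8 from 30.2 to 30.3 Mb held 13 ± 1.00 against 1, and chromosome 12 from 27.1 to 27.2 Mb 16.0 ± 0.0 against 3. In the other direction, the head had 6 strong peaks on chromosome 15 from 10.0 to 10.1 Mb and the posterior trunk libraries had none, and the head had 10 on chromosome 17 from 42.0 to 42.1 Mb, where posterior trunk had 3.67 ± 1.53.

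A window was called when the net number of peaks found in posterior trunk only, less those in head only, passed the replicate spread in all 3 pairs. Of 13044 windows, 139 were called higher in posterior trunk and 100 lower. On chromosome 3 from 23.6 to 23.7 Mb the net number was 11.3 ± 0.58 (SD, 3 pairs), with a largest net of 3 between replicates. The longest run of called windows reached from 35.9 to 36.3 Mb on chromosome 23, with 4 windows and 28.3 net peaks in sum. Without replicate 1 there were 1344 windows, with a threshold of 1 net peak in place of 2 and 2 pairs in place of 3 to pass. Without replicate 2 or 3, where the threshold stayed at 2, there were 315 and 310. The split was 136 higher and 35 lower with the full deposited lists, and 502 higher and 422 lower with 20000 strong peaks. With lists of 100000 peaks it was 202 higher and 207 lower. With peaks ordered by fold enrichment in place of −log10 p, the split was 71 higher and 70 lower, 6 of the 8 top windows lost their call, all but those on chromosomes 8 and 12, and so did chromosome 15 from 10.0 to 10.1 Mb, which also lost it with 20000 strong peaks.

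Against rhombomeres, chromosome 3 from 23.6 to 23.7 Mb again led, with 6 strong peaks in rhombomeres and a net of 12.0 ± 1.00 (SD, 3 pairs). Next came chromosome 23 from 36.0 to 36.1 Mb, with 24.3 ± 1.53 strong peaks in posterior trunk (SD, n = 3) against 8, and chromosome 8 from 30.2 to 30.3 Mb, with 13 ± 1.00 against 2. Rhombomeres had 11 strong peaks on chromosome 14 from 29.4 to 29.5 Mb and 12 on chromosome 17 from 19.5 to 19.6 Mb, where posterior trunk had 2.00 ± 1.00 in each. In all, 107 windows were called higher in posterior trunk and 52 lower. Of these, 64 and 14 were also called against head, with the same 3 posterior trunk libraries in both comparisons. Without replicate 1 there were 1084, and with the full deposited lists the split was 90 higher and 20 lower, but with lists of 100000 peaks 151 and 144. By fold enrichment 75 windows were called, and the windows on chromosomes 3 and 23 lost their call.

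The comparison with anterior trunk isolates the posterior end of the axis. Here 10 windows were called with all 3 pairs, 10 higher in posterior trunk and 0 lower. Replicate 1 alone gave 62 higher and 61 lower, replicate 2 73 and 6, and replicate 3 68 and 13. The split grew more one-sided with the length of the deposited list. The lists held 157921, 206076 and 176479 peaks in replicates 1, 2 and 3 and 148479 in anterior trunk. Single pairs against head and rhombomeres went the same way. A longer list and more open chromatin cannot be told apart from these splits. Chromosome 23 from 36.0 to 36.1 Mb had a net of 8.33 ± 0.58 (SD, 3 pairs), with 11 strong peaks in anterior trunk. Chromosome 3 from 23.6 to 23.7 Mb had 7.67 ± 1.15, chromosome 19 from 19.7 to 19.8 Mb 5.33 ± 2.08, and on chromosome 9 the windows from 14.7 to 14.8 Mb and from 1.9 to 2.0 Mb had 5.0 ± 0.0 and 4.67 ± 1.15. The neighbouring window on chromosome 23, from 36.1 to 36.2 Mb, was as open in anterior trunk, with 21 strong peaks against 16.0 ± 0.0 in posterior trunk, and was not called; it was singled out after its values were seen. The split was 15 higher and 6 lower without replicate 2, 20 and 1 without replicate 3, 212 and 36 without replicate 1 and 30 and 12 with 20000 strong peaks. By fold enrichment 4 windows were called, with the windows on chromosomes 3, 19 and 23 named here and the one from 1.9 to 2.0 Mb on chromosome 9 no longer among them; an overlap of 50% of the peak ended the call on chromosome 3, and 20000 strong peaks those on chromosome 19 and from 14.7 to 14.8 Mb on chromosome 9.

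**Figure D2:**
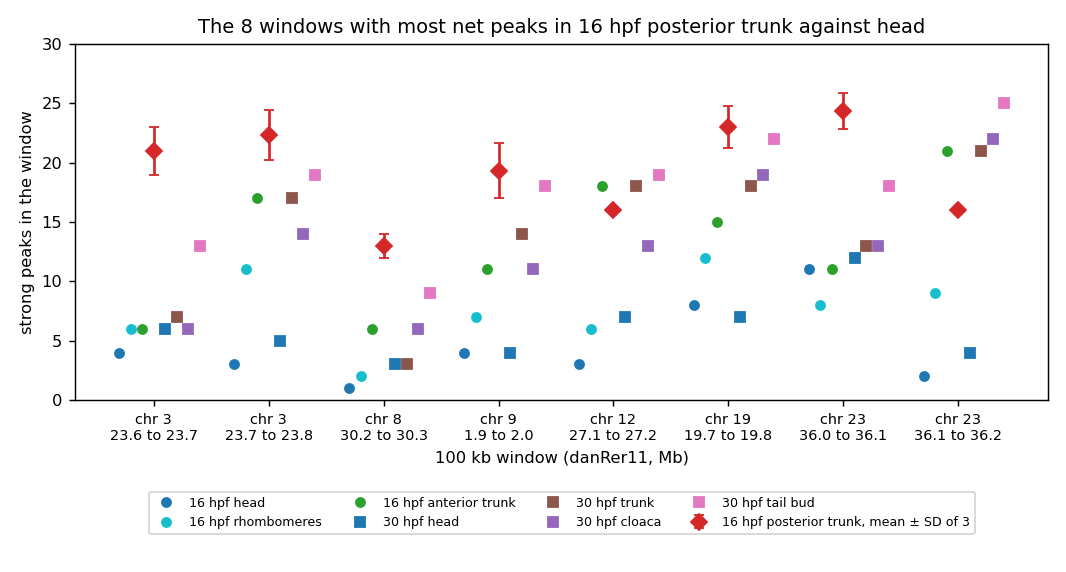
Strong peaks per 100-kb window (number, vertical axis) in the 8 windows with the largest net number of peaks in posterior trunk against head at 16 hpf (danRer11, Mb, horizontal axis), with posterior trunk as the mean and SD of 3 libraries and every other point 1 library. On chromosome 3 from 23.6 to 23.7 Mb posterior trunk stands at 21.0 ± 2.00, above the 13 of the 30 hpf tail bud and the 4 of the 16 hpf head.

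Regions open in all posterior trunk libraries of 16 hpf and absent from head, rhombomeres and anterior trunk numbered 449. The reverse set, strong in those 3 tissues with no peak in any posterior trunk library, held 201. At 30 hpf the posterior set was found most often in the tail bud, at 33.4% of its regions (95% Wilson interval 29.2 to 37.9), then in the cloaca, at 23.6% (19.9 to 27.7). It was found at 14.9% (11.9 to 18.51) in head and 14.3% (11.3 to 17.8) in trunk. The reverse set was found at 96.0% in trunk, 93.0% in head, 80.1% in cloaca and 76.6% in tail bud, and regions strong in all 6 libraries of 16 hpf at 97.9% to 99.3% in the 4 tissues. The sets are not mirror images. The reverse set had to be strong in 3 different tissues, which favours broadly open regions, and the posterior set only in replicates of 1 tissue. Their levels at 30 hpf can therefore not be set against each other, only the tissues within a set. Wilson intervals cover counting error only, and each 30 hpf tissue is 1 library. Without posterior trunk replicate 1 the posterior set held 920 regions, of which 27.1% were found in the tail bud and 22.1% in the cloaca, and the reverse set 303; without replicate 2 the reverse set held 326, and with the full deposited lists 102. With 20000 strong peaks the sets held 21 and 4 regions.

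At 30 hpf the cloaca was compared with the tail bud, the trunk and the head to find what is open in the cloacal region and not in its surroundings. The largest net number against trunk lay on chromosome 2 from 19.4 to 19.5 Mb, with 15 strong peaks in cloaca, 7 in tail bud, 4 in trunk and 3 in head, and 1 to 5 in the libraries of 16 hpf. On chromosome 4 from 51.8 to 51.9 Mb the cloaca had 4 strong peaks and the other 9 fish libraries none. The whole stretch beyond 28 Mb of this chromosome held more strong peaks in cloaca and tail bud, 439 and 417, than in trunk and head, 264 and 255. The window may thus reflect the stretch, and the reason was not tested. Chromosome 10 from 16.8 to 16.9 Mb held 16 strong peaks in cloaca, 12 in tail bud and 7 in trunk. On chromosome 18 from 23.7 to 23.8 Mb head had 17, trunk 13, and cloaca and tail bud 4 each.

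Against tail bud, 83 windows were called higher in cloaca and 47 lower, with net numbers of at most 4 in favour of cloaca. The window on chromosome 3 from 23.6 to 23.7 Mb was lower in cloaca, with 6 strong peaks against 13 in tail bud, as was chromosome 6 from 3.8 to 3.9 Mb, with 3 against 9. Against trunk, 46 windows were higher and 160 lower in cloaca. Chromosome 2 from 19.4 to 19.5 Mb had a net of 9.0 there, 7.0 against head and 3.0 against tail bud, and the windows on chromosome 18 from 23.7 to 23.8 Mb and chromosome 1 from 39.4 to 39.5 Mb each had −7.0. Against head, 234 were higher and 520 lower. In each of these comparisons the larger side was the library with the longer deposited list. The lists held 163902 peaks in head, 153036 in trunk, 141397 in cloaca and 136914 in tail bud. The weakest strong peak had a −log10 p of 19.7, 14.2, 10.8 and 9.18 in the same order. Less open chromatin and a weaker list cannot be told apart from these splits. The cloaca had 22 strong peaks against 4 in head on chromosome 23 from 36.1 to 36.2 Mb, 19 against 7 on chromosome 19 from 19.7 to 19.8 Mb, and 0 against 14 on chromosome 17 from 24.2 to 24.3 Mb.

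These counts had 1 pair each and took their spread from the posterior trunk replicates. The replicate pairs themselves gave 27, 18 and 0 windows against the pairs left, which is low by construction and no background rate. Without replicate 1 the cloacal counts were 881, 992 and 2239 windows. With 20000 strong peaks the split against head was 819 higher and 728 lower. An overlap of 50% of the peak lowered the counts to 32 against tail bud, 20 higher and 12 lower, and to 97 against trunk, 11 and 86. Calls ended by fold enrichment on chromosomes 3, 4, 6 and 10 and with 20000 strong peaks on chromosomes 1, 3, 6, 10 and 17, and against head on chromosome 2; chromosome 3 also lost its call with an overlap of 50% of the peak and chromosome 10 with the full deposited lists. The cloacal comparison with head and the posterior trunk comparison with head use no library in common. They shared 22 higher windows, of 234 and 139, and 37 lower windows, of 520 and 100. Chance sharing among windows with similar numbers of strong peaks, in 50 strata, would give 4.18 and 5.86, a comparison made after the results were seen. Their spread came from the same replicates, so the lists are not fully independent.

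Of the strong peaks found in only 1 tissue of 30 hpf, head had 1737, tail bud 1256, cloaca 1016 and trunk 335. By fold enrichment tail bud had more than head, 1897 against 1794. Of the head-only peaks 76.7% had a peak in the 16 hpf head, 47.7% in rhombomeres, 28.5% ± 2.92 in posterior trunk (SD, n = 3) and 26% in anterior trunk. Of the tail-bud-only peaks 55.8% ± 1.46 had a peak in posterior trunk (SD, n = 3), 44.8% in anterior trunk, 27.8% in rhombomeres and 24.4% in head. Of the cloaca-only peaks 40.6% had a peak in anterior trunk (95% Wilson interval 37.7 to 43.7) and 36.1% ± 6.75 in posterior trunk (SD, n = 3), a difference smaller than the spread between replicates, against 21.7% in rhombomeres and 17.3% in head. Trunk-only peaks were found in rhombomeres at 59.1%, in anterior trunk at 43.9%, in head at 36.1% and in posterior trunk at 29.6% ± 5.02 (SD, n = 3).

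The best-ranked cloaca-only peak lay on chromosome 7 from 4271031 to 4271498, at rank 533 of the strong peaks, and no library of 16 hpf had a peak there. The next, on chromosome 2 from 31714595 to 31715700 at rank 4021, was present in all 3 posterior trunk libraries and in anterior trunk. The third, on chromosome 4 from 54667653 to 54668098 at rank 6590, was absent from all 6 libraries of 16 hpf. It lay beyond 28 Mb of that chromosome, where cloaca had the most strong peaks of all fish libraries. In the tail bud the best-ranked peak, on chromosome 7 from 54948053 to 54948644 at rank 15218, was present in all 6 libraries of 16 hpf. The next, on chromosome 17 from 51522365 to 51522713 at rank 15234, was open in anterior trunk and all posterior trunk libraries. The third, on chromosome 24 from 4249376 to 4249728 at rank 15882, was open in posterior trunk replicates 1 and 3 only. These sets rest on single libraries, and with 20000 strong peaks they shrank to 71 in head, 22 in cloaca, 11 in tail bud and 3 in trunk. Cut to 100000 peaks, the lists gave 2683, 1586, 1985 and 631.

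**Figure D3:**
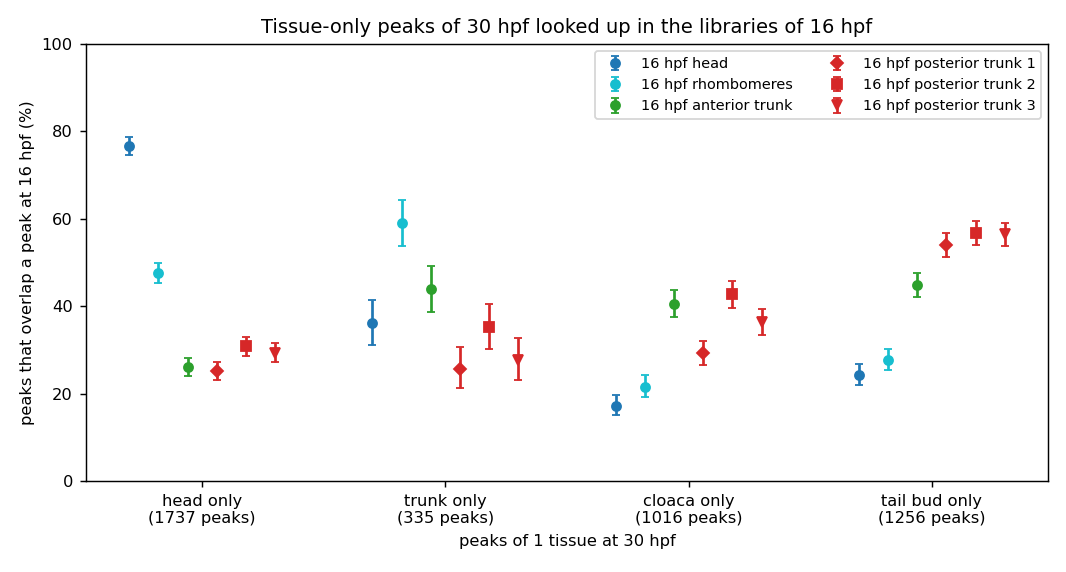
Percent of the peaks found in 1 tissue of 30 hpf only (horizontal axis) that overlap a peak in each library of 16 hpf (vertical axis, %), each point 1 library with its 95% Wilson interval as a bar. Head-only peaks are found in the 16 hpf head at 76.7% and tail-bud-only peaks in posterior trunk at 54.1%, 56.8% and 56.4%.

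Head was the tissue sampled at both stages, and most windows called between the stages had more peaks at 30 hpf, 75 against 9. Each stage was 1 library, and the spread was borrowed from posterior trunk. A replicate pair there gave up to 27 windows, a number that is low by construction and no background rate. The 30 hpf head also had the longer deposited list, 163902 against 145714 peaks. Its weakest strong peak had the higher −log10 p, 19.7 against 16.2. Stage and strength of the list cannot be told apart from this split. On chromosome 23 from 23.1 to 23.2 Mb the head had 13 strong peaks at 30 hpf and 2 at 16 hpf, and on chromosome 22 from 4.1 to 4.2 Mb 7 and 2. Chromosome 22 from 18.2 to 18.3 Mb had 20 and 10, with a net of 6.0. The heads still shared most peaks: 94.5% of the strong peaks of the 30 hpf head had a peak in the 16 hpf head, and 95.9% the other way. Ordered by fold enrichment the split was 53 higher and 15 lower, and the net on chromosome 22 from 18.2 to 18.3 Mb turned to −1.0; the window on chromosome 23 lost its call there and with 20000 strong peaks, and the one from 4.1 to 4.2 Mb with 20000 strong peaks or the full deposited lists. Without posterior trunk replicate 1, 489 windows were called.

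Male and female urogenital sinus at E18.5 differed at few windows, and the largest difference lay on the X chromosome. From 49.6 to 49.7 Mb on X the females had 16 and 15 strong peaks and the males 1 and 1, a net of −13.5 ± 0.58 for male less female (SD, 4 pairs). From 74.7 to 74.8 Mb on X the females had 6 and 7 and the males 1 and 1, and from 49.7 to 49.8 Mb 8 and 7 against 3 and 3. The fourth window lower in males was on chromosome 2 from 139.6 to 139.7 Mb, with 6 and 5 strong peaks in females and 1 and 2 in males. Higher in males were chromosome 2 from 65.3 to 65.4 Mb, with 5 and 5 against 1 and 2, chromosome 2 from 77.6 to 77.7 Mb, with 9 and 7 against 4 and 5, and chromosome 13 from 60.0 to 60.1 Mb, with 6 and 5 against 2 and 2. In the first 10 Mb of the Y chromosome the males had 8 and 7 peaks and the females 0 and 0. Beyond it the males had 7 and 7 and the females 10 and 10, a division that was not planned. All female peaks on Y lay between 90750052 and 90824272, and their source was not tested.

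These 7 windows were called of 20684, all 4 pairs passing. The sexes shared 75.7% ± 3.33 of strong peaks (SD, 8 ordered pairs) and replicates of 1 sex 80.2% ± 1.15 (SD, 4 ordered pairs), so only large differences could be called. Single pairs of a male and a female gave 101 to 225 windows, the females 110 between themselves and the males 16. These counts are not like for like: the females were judged by the male spread, at a threshold of 3 net peaks, and the males by the female spread, at 4. Females had 59 X-linked regions in both libraries and neither male, and males 83 on the same terms. Of the 59, 16 lay between 49638638 and 49764569 and 6 between 74773273 and 74803074. Over the whole genome 2952 regions were male-only and 1565 female-only in this sense, and 1547 lay in male 1 and female 1 and in neither other library, 785 in male 2 and female 2, 593 in male 2 and female 1 and 316 in male 1 and female 2. The direction turned without a female library, to 5679 against 8637 without female replicate 1 and 3894 against 6233 without replicate 2, where female-only rests on 1 library. Strong peaks on X made up 2.61% ± 0.068 in males and 2.71% ± 0.21 in females (SD, n = 2). This difference was smaller than the SD of the females but larger than that of the males. Its exact two-sided permutation p was 1.0, and the smallest p that 2 against 2 allows is 0.333. With the full deposited lists 1 window was higher in males and 3 were lower, and with 20000 strong peaks 10 and 1. The count was 40 without female replicate 1 and 25 without female replicate 2, and the windows on chromosomes 2 and 13 and the one from 49.7 Mb on X lost their call with an overlap of 50% of the peak, with 20000 strong peaks and without either male replicate. That from 74.7 Mb lost it with 20000 strong peaks; the window from 49.6 Mb on X was called in every setting run at 100 kb.

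**Figure D4:**
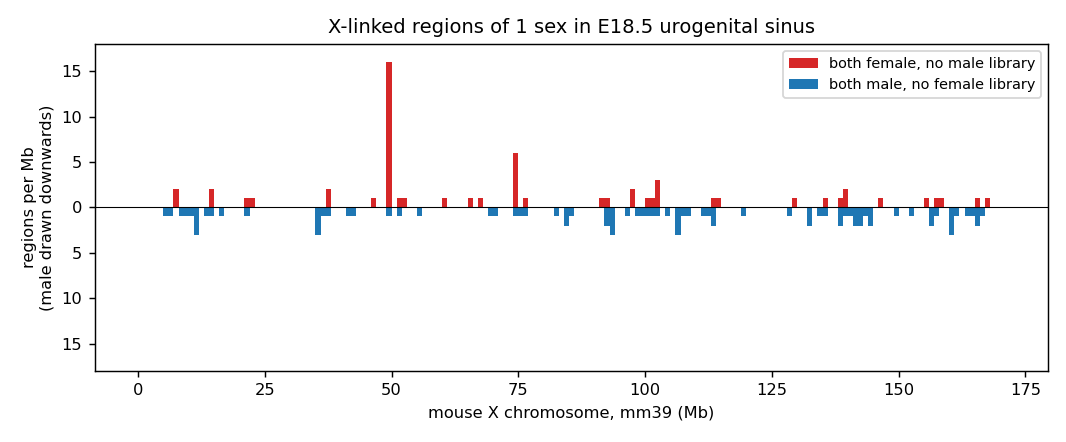
Regions of the mouse X chromosome (mm39, Mb, horizontal axis) with a strong peak in both libraries of 1 sex and no peak in the other sex, as a number per Mb, female-only upwards and male-only downwards. The 16 female-only regions between 49638638 and 49764569 form the tallest bar, and the 6 between 74773273 and 74803074 the next.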

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

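All tests in this part were chosen after the results they bear on had been seen.

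Fish libraries shared more peaks with the head of their own stage, a difference between groups. For each library other than the heads, the percent of strong peaks found in the 30 hpf head less that in the 16 hpf head was 3.14 ± 1.81 points in the libraries of 30 hpf (SD, n = 3) and −1.44 ± 1.18 in those of 16 hpf (SD, n = 5). The difference of 4.58 points had an exact two-sided permutation p of 0.0357, the smallest that 3 against 5 allows. All 8 differences use the same single head library of each stage, so this p holds no variation between head libraries. The groups also hold different tissues, so the p does not separate stage from tissue. The 5 libraries of 16 hpf include 3 replicates of 1 tissue. With posterior trunk as 1 value the difference was 5.04 points with p = 0.1 (exact two-sided permutation), the smallest that 3 against 3 allows. A more complete list for 1 of the heads would by itself move all 8 libraries one way, and 3 lay above 0 and 5 below. This argues against it as the only cause, but the signs are the pattern itself and no separate test. The lowest value of cloaca, tail bud and trunk, 1.71 for the tail bud, lay above the highest of the 5 libraries of 16 hpf, −0.30 for posterior trunk replicate 2. This is the separation that already gave the smallest p, so it is no separate test of the corrected stage. The other tissues of these 3 libraries, or a batch shared with the 30 hpf head, could give the same order. Preparation of each stage in its own batch would give the same p of 0.0357 and cannot be told apart from development, because the labels give no batch; development, which the design names, stays open as well.

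Posterior trunk replicate 1 stood apart from replicates 2 and 3, sharing 97.4% ± 1.23 of strong peaks with them (SD, 4 ordered pairs). Regions strong in both other replicates and missing from replicate 1 numbered 960, and 352 were strong in replicate 1 alone. If the list of replicate 1 were only less complete, regions of its own would seldom be found elsewhere; 55.1% of the 352 had a peak in anterior trunk, close to the 57.8% of the 960, which argues against this. A slightly earlier developmental time of replicate 1 is a candidate explanation: the 960 were found at 30 hpf more often than the 352, by 7.85 to 15.7 points in the 4 tissues, against −4.57 to 2.70 points in the 3 other tissues of 16 hpf. With the full deposited lists these ranges were 10.7 to 15 and −5.48 to 3.90. A different dissection or batch was not tested, and the hypothesis was found and tested on the same data.

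Peaks on unplaced scaffolds lay outside every comparison and were present in all libraries. Fish lists held a mean of 2565.5 such peaks ± 220 (SD, n = 10), between 2370 and 3098. Mouse lists held a mean of 51.75 ± 10.9 (SD, n = 4), between 38 and 61.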

How the results depend on the processing

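Windows of 50 and 200 kb, and all alternatives for the 201 reverse regions, the difference between the heads, the mouse regions of 1 sex and the tail bud and cloaca shares, were chosen after the results were seen; the others were planned. Of 156 values for the main results, 70 stayed within 1.5 times the main count or 1 SD, 82 moved and 4 lost their p threshold. In the order below, the comparisons are posterior trunk against head, rhombomeres and anterior trunk, cloaca against tail bud, trunk and head, head at 30 against 16 hpf, and male against female, with 239, 159, 10, 130, 206, 754, 84 and 7 windows called.

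With the full deposited lists male against female gave 4 windows and the reverse set 102 regions. Lists of 100000 peaks gave 409, 295, 27, 218, 345 and, for the heads, 180 windows; the posterior set rose from 449 to 700, the reverse set to 426, and tissue-only peaks to 2683 in head, 1586 in cloaca, 1985 in tail bud and 631 in trunk. With 20000 strong peaks the counts were 924, 764 and 42, then 313 against trunk, 1547 against head, 160 between the heads and 11 in mouse; the sets shrank to 21 and 4 regions, tissue-only peaks to 71, 22, 11 and 3, the mouse regions from 2952 male-only and 1565 female-only to 397 and 31, and the replicate overlap rose from 98.2% to 99.95%. By fold enrichment the posterior trunk counts were 141, 75 and 4, mouse 3, and tail-bud-only peaks 1897. An overlap of 50% of the peak gave 118 and 77, cloaca 32 and 97 against tail bud and trunk, heads 41, mouse 2, head-only 3033 and trunk-only 504 peaks, and a replicate overlap of 95.9%. Windows of 50 kb gave 686, 515, 58, 589, 693, 1887, 321 and 4, and windows of 200 kb 364, 252, 27, 245, 353, 159 for the heads and 1 in mouse. Mouse autosomes alone gave 4.

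The threshold itself moved with the setting: from 2 peaks in fish and 3 in mouse it fell to 0 and 1 with 20000 strong peaks, and in fish to 1 with windows of 50 kb or without posterior trunk replicate 1, which by construction lets more windows pass; without a replicate fewer pairs must also pass. It rose to 3 in fish and 4 in mouse at an overlap of 50%, and in mouse to 5 with windows of 200 kb, which lets fewer pass. Without either male replicate it rose to 4, yet 8 windows passed with 2 pairs in place of 4. For the other shifts the cause was not tested. In 7 of 90 splits the other side became the larger. Posterior trunk against head went from 139 higher and 100 lower to 202 and 207 at 100000 peaks, and cloaca against head from 234 and 520 to 819 and 728 at 20000 strong peaks. Male against female went from 3 and 4 to 10 and 1 at 20000 strong peaks, 5 and 3 without male replicate 2 and 3 and 1 on autosomes, and male-only regions fell below female-only ones without either female replicate, 5679 against 8637 and 3894 against 6233. An overlap of 50% gave 66 and 457 for cloaca against head and 0 and 2 in mouse, and lists of 100000 peaks 151 and 144 for posterior trunk against rhombomeres, 107 and 52 in the main setting.

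Leaving out 1 replicate gave 310 to 1344, 206 to 1084, 21 to 248, 130 to 881, 206 to 992, 754 to 2239, 84 to 489 and 8 to 40 windows in the same order; the highest fish counts were without posterior trunk replicate 1 and the highest mouse count without female replicate 1. The posterior set ranged from 552 to 920 regions, the reverse set from 282 to 326, male-only regions from 3894 to 8694, female-only from 3194 to 8637 and the replicate overlap from 97.4% to 99.9%. The difference between the heads ranged from 4.61 to 4.87 points with an exact two-sided permutation p of 0.0571, the smallest that the 7 libraries left allow. With posterior trunk as 1 value it was 5.04 points with p = 0.1 (exact two-sided permutation). Its p stayed at 0.0357 in the other settings with all libraries, where it lay between 1.58 and 5.62 points. In the posterior set, tail bud stayed above cloaca and cloaca above head and trunk in all 8 settings, the main one included. Head and trunk changed order, from 14.9% and 14.3% in the main setting to 9.52% and 14.3% with 20000 strong peaks.

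Of 111 named windows with 895 values, 738 kept their call, 155 lost it and 2 reversed: mouse chromosome 2 from 139.6 Mb, at 0.5 with 20000 strong peaks against −4.25, and the heads on chromosome 22 from 18.2 Mb, at −1.0 by fold enrichment against 6.0. Of 88 values for other shares, 65 stayed and 23 moved.

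The mouse replicate numbers are not stated to pair the sexes. With the replicate block, only the 2 same-numbered pairs, 8 windows were called, 4 higher and 4 lower, against 7. The deviations of same-numbered libraries correlated at 0.060 over 146738 regions, with only 2 pairs. This does not exclude an effect of the number. Regions of same-numbered libraries alone numbered 1547 and 785, and those of crossed libraries 593 and 316. Both lists with number 1 were also longer, 111033 in male and 103874 in female against 89833 and 77875 peaks. A batch and the strength of the list cannot be told apart here.

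Not run for lack of an annotation or genome of the builds were the linking distance of 10 kb, the hoxda and HoxD landscapes, hox promoters, gene lists and motifs. The list of 100000 peaks was void in mouse, whose lists were already shorter, and the 50% overlap was not applied to merged regions. Without read counts, depth limits all counts in an unknown way.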

Other observations

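The tests of splits and of hox chromosomes in this part were chosen after the results were seen, and no value here was planned.

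Some windows with many peaks in posterior trunk at 16 hpf had few in all 4 tissues of 30 hpf. On chromosome 9 from 14.7 to 14.8 Mb the posterior trunk had 13.7 ± 0.58 strong peaks (SD, n = 3), while the other 16 hpf libraries had 3 to 5 and the 30 hpf libraries 7 in head, 3 in cloaca, 2 in tail bud and 3 in trunk. On chromosome 5 from 68.8 to 68.9 Mb it had 10.3 ± 0.58, against 4 to 6 in the other 16 hpf libraries and 2 in each of the 4 tissues of 30 hpf. By contrast, chromosome 9 from 1.9 to 2.0 Mb and chromosome 12 from 27.1 to 27.2 Mb had 18 and 19 strong peaks in the 30 hpf tail bud. Each 30 hpf value is 1 library.

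Tissue-only peaks of 30 hpf lay closer together than chance placement gives in head. In head, 31 windows of 100 kb held 3 or more of them, against a mean of 10.5 and a highest value of 21 in 1000 random draws. In cloaca 7 did, against a mean of 1.79 and a highest value of 7, in tail bud 4, against a mean of 3.39 and a highest value of 11, and in trunk 1, against a mean of 0.071 and a highest value of 2. Beyond 28 Mb of chromosome 4 the strong peaks numbered 439 in cloaca, 417 in tail bud, 264 in trunk and 255 in head at 30 hpf. At 16 hpf they numbered 420 in anterior trunk, 385, 357 and 366 in the posterior trunk replicates, 363 in head and 323 in rhombomeres. The division at 28 Mb was chosen after the values were seen.

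The 6 libraries of 16 hpf were split into 3 and 3 in all 10 ways. The split of posterior trunk from the rest gave 650 regions, 1 of the 10 splits with as many, and the highest of the others gave 54. With 10 splits no share under 0.05 can be reached. Every other split parts the posterior trunk replicates, and replicates 2 and 3 share 99.9% of strong peaks, so few regions could separate them. The 54 came from the split with replicates 2 and 3 and anterior trunk on 1 side, 48 and 6 in its directions. The gap between 650 and 54 could arise from the likeness of replicates alone, so it does not test a difference between tissues.

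A hypothesis of its own was that the windows most open in posterior trunk against head lie on the chromosomes that carry hox genes, the regulators of position along the body axis. Neighbouring called windows were joined to domains, and the 10 with the largest summed net number were compared with 100000 random draws of 10 windows. They touched 6 of the 7 chromosomes with hox genes in the name table, with 7 of the 10 domains on them, where random draws touched 2.31 on average, and 0.191% of draws touched as many (one-sided permutation p = 0.0019). Drawn from windows with similar numbers of strong peaks, 0.194% of draws did. The 10 domains lower in posterior trunk touched 1 or 2, depending on ties, as did at least 76.6% of draws. This may point to hox clusters, but a chromosome does not place a gene in a window, and 6 of the top 8 windows lost their call with peaks ordered by fold enrichment. For cloaca against head the number touched was between 3 and 5, depending on how 7 domains tied at the last place were chosen, and 42.1% to 2.37% of draws touched as many, so that this comparison stays open.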
